A study of Mus musculus with 12 samples.

How the data were processed

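RAW264.7 cells, a mouse monocyte-macrophage line, had been cultured without or with RANKL, the cytokine that drives osteoclast formation, at 40 ng/mL, and harvested on day 5, per the labels. Total RNA was labelled with biotin and hybridised to Illumina BeadChips, per the labels' protocols. The series holds 12 arrays on 2 BeadChips. The labels name 3 cell groups: osteoclast precursors (OP, no RANKL), intermediate osteoclasts (IO) and multinuclear osteoclasts (OC), the latter pair from RANKL-treated cultures. On 9 arrays the source name and the cell subtype name a single group, which gave 3 OP, 3 IO and 3 OC arrays. The ligand separates OP from the RANKL-treated groups but not IO from OC. The titles hold nt, osteo and trap, which were read as OP, IO and OC from the other labels. On the other 3 arrays the title, read in this way, and the cell subtype name different groups, so they entered no comparison between groups. The series describes 4 replicates of each condition. The cell subtypes give that number for every group, and the titles do not. The labels call the arrays of a group experimental replicates and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

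The deposited intensity of each probe is the mean brightness of its beads, summarised by the authors in GenomeStudio 2011.1 per the submitters' processing notes, with no background subtracted in the table used here (lowest value 82.3). The deposited detection p-value gives, for each probe and array, how the probe compares with the negative control beads. The whole-series table holds 45281 probes, and its values equal those of the 12 single-array files with 0 differences. The authors' processed log2 values cover 23624 probes, exactly those with a detection p under 0.1 on at least 2 arrays when tested on the files. They hold the same sorted values on every array, as quantile normalization gives, with a median of 6.99 and a lowest value of 6.51. The steps behind them are not given in the sources used here. The authors' values served as an alternative. The negative control probes were not used here, so the background was inferred from the detection p-values.

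Intensities of the 9 arrays were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 with an offset of 16, which shrinks the fold changes of dim probes. Probes were named through the platform annotation, with symbols brought up to date through gene identifiers, accessions and synonyms of the GRCm38.p6 RefSeq gene table, which was used for names only. In that annotation 20075 probes have 1 gene symbol, 0 have several and 3549 probes with processed values have none. Symbols were updated for 1553 probes, and 18 matched nothing in the table and kept their name. Probes with a detection p under 0.01 on at least 3 of the 9 arrays were retained (15567, of which 1743 carried no symbol), and each gene was represented by its probe with the highest mean, leaving 8967 genes. No coordinates are given because no genome build is given in the sources used here. The number of arrays limits the precision. Between 14210 and 15291 probes per array were above background among the 9 arrays, and the median standard error of a log2 fold change was 0.135 for OC vs OP.

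All 9 arrays entered one limma fit (lmFit and eBayes, two-sided), with contrasts OC minus OP, IO minus OP and OC minus IO, a moderated F-test over the groups, and Benjamini-Hochberg adjustment over genes with a threshold of 0.05. Every adjusted p of a gene is from this fit. A gene with a detection p of 0.01 or more on every array of a group has only a bound there. Its fold is given as at least N-fold, from the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes (log2 4.70 to 4.86) and the probe's own. Where several probes of a gene passed the test, 5 of 442 other probes had the opposite direction in OC vs OP, 96 of 1614 in IO vs OP and 115 of 1562 in OC vs IO.

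Before the data were examined, 24 gene lists were fixed and tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over all lists and contrasts, for lists with at least 5 measured members. Of these, 21 could be tested. Neutrophil markers (2 measured), fibroblast and osteoblast markers (2 measured) and lymphocyte markers (1 measured) were too few. The genes named were also chosen by a rule set then: per contrast the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap, leaving out clone names; up to 2 rises and 2 falls per list; and Acp5, Ctsk, Mmp9, Calcr, Nfatc1, Dcstamp, Ocstamp, Atp6v0d2, Oscar, Itgb3 and Tnfrsf11a in every contrast. The text gives a selection of the genes this rule names, made after their values were seen. Calcr had no named probe here, and the Itgb3 probe did not pass the detection filter.

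The fit was tested on simulated data. The draws started from values of the 8967 genes retained, so background correction, normalization, the detection filter and the choice of probe were not tested. In 20 draws of the OC vs OP comparison with 8967 genes and 200 changed, the fit recovered 48.3% of genes changed by a log2 of 0.5, 99.7% of those changed by 1 and 100% of those changed by 2, with 5.53% false calls. Alternatives were the authors' values, no background correction, median scaling in place of quantile normalization, an offset of 50, other probe filters, all probes, another variance model, fitting only the groups compared, BeadChip or replicate number as a block, grouping all 12 arrays by title or by cell subtype, an estimated inter-gene correlation and leaving out each array. The 6 arrays of BeadChip 1 alone were an alternative chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.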

Results

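Gene expression was measured on BeadChips in RAW264.7 cells, a mouse macrophage line that forms osteoclasts when given RANKL. The comparisons cover 9 arrays: 3 labelled osteoclast precursor (OP, no RANKL), 3 labelled intermediate osteoclast (IO) and 3 labelled multinuclear osteoclast (OC), the IO and OC arrays from cultures with RANKL at 40 ng/mL, all harvested on day 5. The title of the series names functional reprogramming during osteoclast development as its subject. Between 14210 and 15291 probes per array were above background, and 8967 genes were tested. BeadChip 1 held 2 arrays of each group and BeadChip 2 held 1. Of 31 known osteoclast genes, 19 were lower and 5 higher on the arrays labelled OC than on those labelled IO, and 7 did not pass the test (camera adjusted p = 0.000159, and adjusted p = 0.060 with an estimated correlation). Directions below are between arrays as labelled.

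Across the 3 groups 5379 of 8967 genes differed (limma moderated F-test, adjusted p under 0.05). With BeadChip as a block the number was 5634, and on BeadChip 1 alone 4186. Across genes, which are not independent replicates, arrays of 1 group correlated at 0.985 to 0.995. OP and OC arrays correlated at 0.975 to 0.984, OC and IO arrays at 0.940 to 0.954, and OP and IO arrays at 0.927 to 0.940.

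The comparison of OC with OP asks how cells labelled multinuclear osteoclast differ from untreated precursors. On the arrays labelled OC 20 of 31 osteoclast genes, 18 of 36 DNA replication genes and 18 of 27 endoplasmic reticulum stress genes rose, and 13 of 17 glycolysis genes fell. With an estimated correlation the osteoclast list alone of these kept its call (adjusted p = 0.00419), against adjusted p = 0.104 for DNA replication, adjusted p = 0.064 for endoplasmic reticulum stress and adjusted p = 0.0831 for glycolysis. Slc9b2, a sodium/proton antiporter of osteoclasts, rose 8.34-fold (log2 fold change 3.06 ± 0.12, SE, n = 3 arrays per group, limma adjusted p = 1.84e-09). Dcstamp, needed for the fusion of osteoclast precursors, rose at least 5.7-fold, since it was not above background on the OP arrays. Scin, an actin-severing protein, rose at least 5.98-fold under the same limit. Mmp9, a matrix metalloproteinase, rose 6.27-fold. Ctsk, the collagen-degrading cathepsin, rose 2.65-fold, Acp5, tartrate-resistant acid phosphatase, 3.29-fold, Oscar, an osteoclast receptor, 3.57-fold, and Nfatc1, the transcription factor that directs osteoclast formation, 2.22-fold. Tnfrsf11a, the RANKL receptor, rose 2.24-fold and Ocstamp at least 1.76-fold. Atp6v0d2 was not above background on the OP arrays. Its log2 mean of 4.84 on the OC arrays did not exceed the bound for the OP arrays, so no fold is given. Its fitted log2 difference of 0.43 ± 0.15 (adjusted p = 0.0557) did not pass the test. It passed with BeadChip as a block (0.0489), with the replicate block (0.047), and without IO replicate 1 (0.0376), IO replicate 3 (0.046) or OC replicate 3 (0.0326), over a range of 0.0326 to 0.854. The early growth response factors Egr2, Egr1 and Egr3 rose 7.17-fold, 6.89-fold and 6.40-fold, and the chemokine Cxcl2 7.86-fold.

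Of 31 osteoclast effector and regulator genes measured, 20 rose and 0 fell (adjusted over the list alone, 21 rose and 1 fell; camera adjusted p = 1.94e-16, and adjusted p = 0.00419 with an estimated correlation). DNA replication genes rose in 18 of 36 cases and fell in 0 (adjusted over the list alone, 23 and 0; camera adjusted p = 7.54e-11, and adjusted p = 0.104 with an estimated correlation), with Mcm6, a subunit of the replicative helicase, 1.86-fold higher and the chromatin assembly factor Chaf1a 1.83-fold. In the mitosis list 5 of 27 rose, Mki67 among them by 2.01-fold (adjusted over the list alone, 5; camera adjusted p = 0.0213, and adjusted p = 0.447 with an estimated correlation). Endoplasmic reticulum stress genes rose in 18 of 27 cases (adjusted over the list alone, 19; camera adjusted p = 8.05e-09, and adjusted p = 0.064 with an estimated correlation), among them Ppp1r15a, 2.15-fold, and the disulfide isomerase Pdia4, 1.99-fold. Cytokines and chemokines rose in 10 and fell in 4 of 20 cases (adjusted over the list alone, 10 and 4; camera adjusted p = 0.00321, and adjusted p = 0.0826 with an estimated correlation), Ccl7 rising 3.76-fold and Cxcl16 falling 2.13-fold. In the fusion, podosome and adhesion list 7 of 35 rose and 1 fell (adjusted over the list alone, 7 and 1; camera adjusted p = 0.0315, and adjusted p = 0.39 with an estimated correlation). That call was lost with the arrays grouped by title (0.0741), detection on all 9 arrays (0.104), median scaling (0.0532), no background correction (0.0648), the authors' values (0.0611), the arrays grouped by cell subtype (0.064) and without OP replicate 1 (0.0682), over a range of 0.0145 to 0.104.

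Glycolysis genes fell in 13 of 17 cases and rose in 1 (adjusted over the list alone, 13 and 1; camera adjusted p = 5.63e-08, and adjusted p = 0.0831 with an estimated correlation). Eno2, an enolase, fell 4.29-fold and Slc2a1, a glucose transporter, 2.02-fold, while the enolase Eno3 rose 2.32-fold. The 10 largest falls included Mgarp (6.12-fold), Ankrd37 (5.69-fold), Ndrg1 (4.14-fold), Ak4 (4.04-fold) and Egln3, an oxygen-dependent prolyl hydroxylase (at least 4.06-fold, not above background on the OC arrays). P4ha2 fell at least 4.54-fold and Adm at least 2.9-fold under the same limit, and Serpinf1 fell 3.75-fold. Toll-like and other innate receptors fell in 9 of 25 cases and rose in 1 (adjusted over the list alone, 12 and 2; camera adjusted p = 0.000878, and adjusted p = 0.258 with an estimated correlation), and antigen presentation genes fell in 8 of 17, H2-K1 by 2.11-fold (adjusted over the list alone, 11 fell and 1 rose; camera adjusted p = 0.000417, and adjusted p = 0.197 with an estimated correlation). Cytosolic ribosomal proteins fell in 3 of 49 cases (adjusted over the list alone, 1; camera adjusted p = 0.0439, and adjusted p = 0.459 with an estimated correlation). That ribosomal share is below the share of all genes that fell, 876 of 8967, and the list median was a log2 of -0.083. The ribosomal call was lost with the arrays grouped by title (0.0558) and without OC replicate 3 (0.116), OP replicate 1 (0.0913) or OP replicate 2 (0.124), over a range of 3.61e-07 to 0.124. The mitosis call was lost with the arrays grouped by cell subtype (0.544) and without OC replicate 1 (0.0511) or OP replicate 2 (0.0521), over a range of 0.00577 to 0.544. That grouping also ended the call of the innate receptors (0.0594, over a range of 0.000254 to 0.0594). The macrophage list did not shift (3 rose and 5 fell of 22, and 4 and 6 adjusted over the list alone; camera adjusted p = 0.471).

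In all, 1802 genes changed in OC vs OP, 926 higher and 876 lower, and 181 of them at least 2-fold (123 higher, 58 lower). The number was 2056 with BeadChip as a block and 1053 on BeadChip 1 alone, and the lists called were 10 of 21, 10 with that block and 10 on BeadChip 1 alone. Median scaling gave 1033 genes, of which 86.8% were higher against 51.4% here, with a median shift of all genes of 0.171 on the log2 scale, so the balance of rises and falls rests on the scaling. Without OC replicate 1 the number was 974, and without OP replicate 1 it was 999. Grouping all 12 arrays by cell subtype left 15 genes (limma, 1017 at an unadjusted p under 0.05).

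The comparison of IO with OP asks how cells labelled intermediate differ from precursors. Dcstamp rose at least 49.4-fold (log2 mean 4.53 ± 0.22 on OP and 10.47 ± 0.19 on IO arrays, SD, n = 3 each, limma adjusted p = 8.98e-13). Mmp9 rose 13.1-fold, Oscar 9.83-fold, Ctsk 5.73-fold, Acp5 5.12-fold, Ocstamp at least 3.88-fold, Atp6v0d2 at least 2.25-fold, Tnfrsf11a 2.03-fold and Nfatc1 1.67-fold. Mustn1, known from muscle and skeletal tissue, rose 65-fold, Sphk1, a sphingosine kinase, at least 38.6-fold, the kinase Matk at least 23.2-fold, the metallothionein Mt3 at least 18.4-fold and Cd200, a membrane glycoprotein, at least 10.7-fold. Il1rn, the interleukin 1 receptor antagonist, rose 15.7-fold. The histone gene H4c8 rose 19.9-fold, which is uncertain because near-identical copies share its sequence. Among the 10 largest falls were those of Tmem176b (18.1-fold), Fpr2, a formyl peptide receptor (16.1-fold), Slpi (15.2-fold), the acute phase gene Saa3 (15.2-fold), Clec4e (10.4-fold), Acod1, the enzyme that makes itaconate (10.1-fold), and complement C3 (9.74-fold).

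**Figure D1:**
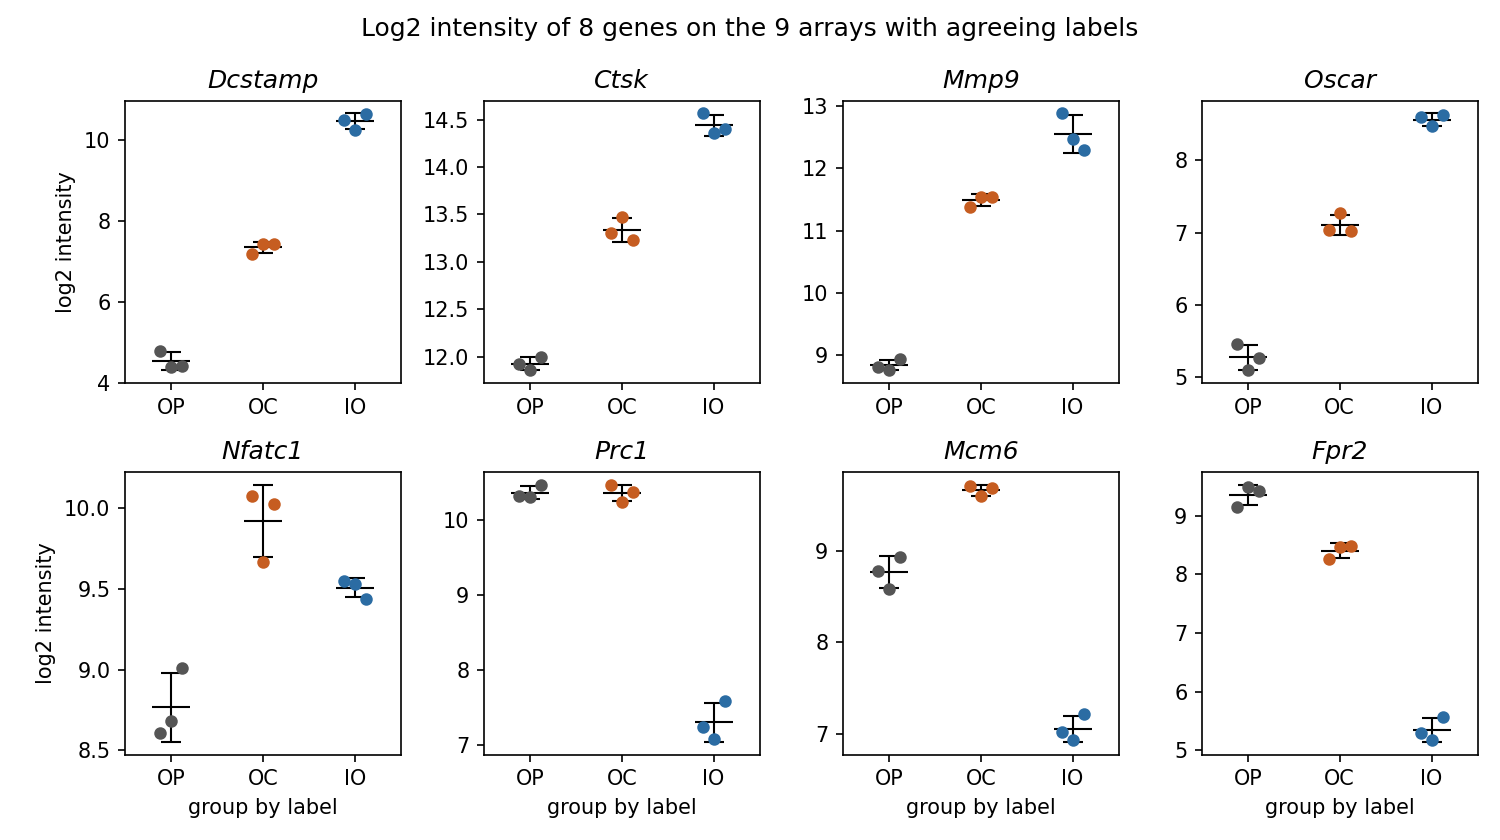
Log2 intensity (vertical axis) of 8 genes on 3 OP, 3 OC and 3 IO arrays, grouped by label (horizontal axis), with a point per array and the mean and SD as lines; vertical axes differ between panels and do not start at 0. Dcstamp means were 4.53, 7.36 and 10.47 on OP, OC and IO arrays, and Mcm6 means 8.77, 9.66 and 7.06.

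Of 31 osteoclast genes 23 rose and 2 fell (adjusted over the list alone, 23 and 2; camera adjusted p = 8.59e-12, and adjusted p = 0.0057 with an estimated correlation). Of 19 subunits of the V-ATPase, the proton pump, 17 rose (adjusted over the list alone, 17; camera adjusted p = 1.47e-06, and adjusted p = 0.0831 with an estimated correlation), Tcirg1, its osteoclast subunit, by 4.52-fold. Fusion, podosome and adhesion genes rose in 16 and fell in 5 of 35 cases (adjusted over the list alone, 16 and 5; camera adjusted p = 0.00455, and adjusted p = 0.274 with an estimated correlation). Dendritic cell markers rose in 4 of 5 cases, Cd83 by 2.53-fold and Cd80 by 2.36-fold (adjusted over the list alone, 4; camera adjusted p = 0.012, and adjusted p = 0.094 with an estimated correlation), a call lost without a filter on detection (0.123, over a range of 0.0111 to 0.123).

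In the mitosis list 26 of 27 fell and 0 rose (adjusted over the list alone, 27 and 0; camera adjusted p = 1.94e-16, and adjusted p = 0.064 with an estimated correlation), the spindle gene Prc1 by 8.39-fold and Nusap1 by 7.50-fold. DNA replication genes fell in 34 of 36 cases (adjusted over the list alone, 35; camera adjusted p = 1.94e-16, and adjusted p = 0.0831 with an estimated correlation), Rrm2 by 5.70-fold and the helicase subunit Mcm7 by 5.50-fold. Macrophage genes fell in 16 and rose in 2 of 22 cases (adjusted over the list alone, 16 and 2; camera adjusted p = 5.18e-06, and adjusted p = 0.0831 with an estimated correlation), Cx3cr1 by 6.39-fold and Adgre1, a macrophage surface receptor, by 5.45-fold, while Spi1 rose 2.21-fold. Toll-like and other innate receptors fell in 21 and rose in 2 of 25 cases (adjusted over the list alone, 21 and 2; camera adjusted p = 1.18e-08, and adjusted p = 0.0831 with an estimated correlation), with Clec7a, the beta-glucan receptor, rising 5.09-fold. Antigen presentation genes fell in 10 and rose in 1 of 17 cases, Cd74 by 3.19-fold (adjusted over the list alone, 10 and 1; camera adjusted p = 0.00321, and adjusted p = 0.272 with an estimated correlation). Endoplasmic reticulum stress genes fell in 16 and rose in 2 of 27 cases (adjusted over the list alone, 16 and 2; camera adjusted p = 0.00507, and adjusted p = 0.238 with an estimated correlation). That call was lost, and its direction turned, with the arrays grouped by cell subtype (0.946, over a range of 0.00121 to 0.946). Cytosolic ribosomal proteins fell in 15 and rose in 1 of 49 cases (adjusted over the list alone, 14 and 1, with camera adjusted p = 0.012, and adjusted p = 0.359 with an estimated correlation). The share that fell is near that of all genes, 2285 of 8967, and the list median was a log2 of -0.204.

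In all, 4579 genes changed in IO vs OP, 2294 higher and 2285 lower, and 1215 at least 2-fold (625 higher, 590 lower). The number was 4792 with BeadChip as a block and 3664 on BeadChip 1 alone, and 11 of 21 lists were called, 11 with that block and 10 on BeadChip 1 alone. Median scaling gave 3132 genes, 59% of them higher against 50.1% here (1848 higher, 1284 lower). Grouping all 12 arrays by cell subtype left 0 genes (limma, 1129 at an unadjusted p under 0.05), so each gene call above was lost under it. Because it mixes arrays whose labels conflict, this loss says little about the calls.

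The comparison of OC with IO sets the RANKL-treated groups side by side. Among osteoclast genes, Dcstamp was 8.67-fold lower on the arrays labelled OC (log2 fold change -3.12 ± 0.14, SE, n = 3 per group, limma adjusted p = 1.12e-09), Oscar 2.75-fold, Ocstamp 2.20-fold, Ctsk 2.16-fold, Mmp9 2.09-fold and Acp5 1.56-fold. Atp6v0d2, near background on the OC arrays, had a log2 fold change of -1.18 ± 0.15. The Acp5 call was lost with median scaling (adjusted p = 0.0767) and with the arrays grouped by cell subtype (0.81), over a range of 0.000696 to 0.81. Mmp14 was 2.24-fold higher. Nfatc1 was 1.33-fold higher (adjusted p = 0.0248), a call lost with median scaling (0.0787), with the arrays grouped by cell subtype (0.787), on BeadChip 1 alone (0.127) and without IO replicate 2 (0.0526), IO replicate 3 (0.0624), OC replicate 1 (0.105) or OC replicate 3 (0.0848), over a range of 0.00222 to 0.787. Tnfrsf11a had a log2 difference of 0.14 ± 0.20 (adjusted p = 0.574). Sphk1 was 19-fold lower, Mustn1 14.5-fold, Mt3 12.3-fold, Cd200 10.6-fold, Vwf 9.24-fold and Pdpn 8.31-fold. Tmem176b was 10.3-fold higher, Gpr84 9.84-fold, Cx3cr1, the fractalkine receptor, 9.32-fold, Prc1 8.37-fold, Lmnb1, lamin B1, 8.34-fold and Fpr2 8.33-fold. Histone genes H2ac15, H2ac12 and H2ac22 were 10.3-fold, 10.2-fold and 8.26-fold higher, which is uncertain because near-identical copies share sequence.

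All 27 mitosis genes and all 36 DNA replication genes were higher on the OC arrays (adjusted over the list alone, 27 and 36; camera adjusted p = 3.61e-20 and 7.80e-24, and adjusted p = 0.060 and 0.064 with an estimated correlation), Mcm10 by 7.81-fold and Uhrf1 by 7.07-fold. Osteoclast genes were lower in 19 and higher in 5 of 31 cases (adjusted over the list alone, 20 and 6; camera adjusted p = 0.000159, and adjusted p = 0.060 with an estimated correlation). That call was lost with the arrays grouped by cell subtype (0.112, over a range of 6.04e-06 to 0.112). V-ATPase subunits were lower in 15 of 19 cases (adjusted over the list alone, 15; camera adjusted p = 2.69e-06, and adjusted p = 0.0831 with an estimated correlation). Endoplasmic reticulum stress genes were higher in 22 and lower in 1 of 27 cases (adjusted over the list alone, 22 and 1; camera adjusted p = 6.72e-09, and adjusted p = 0.064 with an estimated correlation), the chaperone Calr by 4.35-fold and Herpud1 by 3.91-fold. Macrophage genes were higher in 16 and lower in 2 of 22 cases (adjusted over the list alone, 16 and 2; camera adjusted p = 4.29e-06, and adjusted p = 0.0831 with an estimated correlation), and innate receptors higher in 18 and lower in 2 of 25 (adjusted over the list alone, 18 and 2; camera adjusted p = 6.72e-07, and adjusted p = 0.104 with an estimated correlation). Interferon-induced genes were higher in 7 and lower in 1 of 13 cases, Bst2 by 3.65-fold (adjusted over the list alone, 8 and 1; camera adjusted p = 0.0102, and adjusted p = 0.0938 with an estimated correlation), a call lost with the arrays grouped by cell subtype (0.064, over a range of 0.005 to 0.064). Genes of the NF-kB pathway were higher in 11 and lower in 2 of 23 cases, Nfkbia by 2.80-fold (adjusted over the list alone, 11 and 2; camera adjusted p = 0.0156, and adjusted p = 0.0896 with an estimated correlation). Dendritic cell markers were lower in 4 of 5 cases (adjusted over the list alone, 4; camera adjusted p = 0.028, and adjusted p = 0.127 with an estimated correlation), a call lost with the arrays grouped by title (0.0975) or by cell subtype (0.193) and without a filter on detection (0.212), over a range of 0.021 to 0.212. Fusion, podosome and adhesion genes were lower in 14 and higher in 4 of 35 (adjusted over the list alone, 14 and 4; camera adjusted p = 0.035, and adjusted p = 0.39 with an estimated correlation). That call was lost with the arrays grouped by title (0.122) or by cell subtype (0.157), detection on all 9 arrays (0.12), BeadChip 1 alone (0.13) and without IO replicate 3 (0.0874), over a range of 0.00842 to 0.157.

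Glycolysis genes were lower in 9 and higher in 2 of 17 cases, Eno2 by 3.27-fold (adjusted over the list alone, 9 and 2; camera adjusted p = 0.0403, and adjusted p = 0.39 with an estimated correlation). That call was lost with the arrays grouped by title (0.0705) and without IO replicate 3 (0.0873), OC replicate 1 (0.0554) or OC replicate 2 (0.0618), over a range of 0.0106 to 0.0873. Oxidative phosphorylation subunits were lower in 20 and higher in 4 of 66 cases (adjusted over the list alone, 19 and 3; camera adjusted p = 0.0429, and adjusted p = 0.482 with an estimated correlation). Their share of lower genes is near that of all genes, 2304 of 8967, and the list median was a log2 of -0.159. The oxidative phosphorylation call was lost with median scaling (0.0532) and without IO replicate 1 (0.108), IO replicate 2 (0.063), OC replicate 2 (0.0533), OC replicate 3 (0.0826) or OP replicate 2 (0.0511), over a range of 0.0071 to 0.108.

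In all, 4417 genes differed in OC vs IO, 2113 higher and 2304 lower, and 969 at least 2-fold (535 higher, 434 lower). The number was 4619 with BeadChip as a block and 3339 on BeadChip 1 alone, and 13 of 21 lists were called, 13 with that block and 12 on BeadChip 1 alone. Median scaling gave 2851 genes, 62.7% of them higher against 47.8% here (1789 higher, 1062 lower). Grouping all 12 arrays by cell subtype left 0 genes (limma, 189 at an unadjusted p under 0.05), so each gene call above was lost under it. This loss too says little about the calls, for the same reason.

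**Figure D2:**
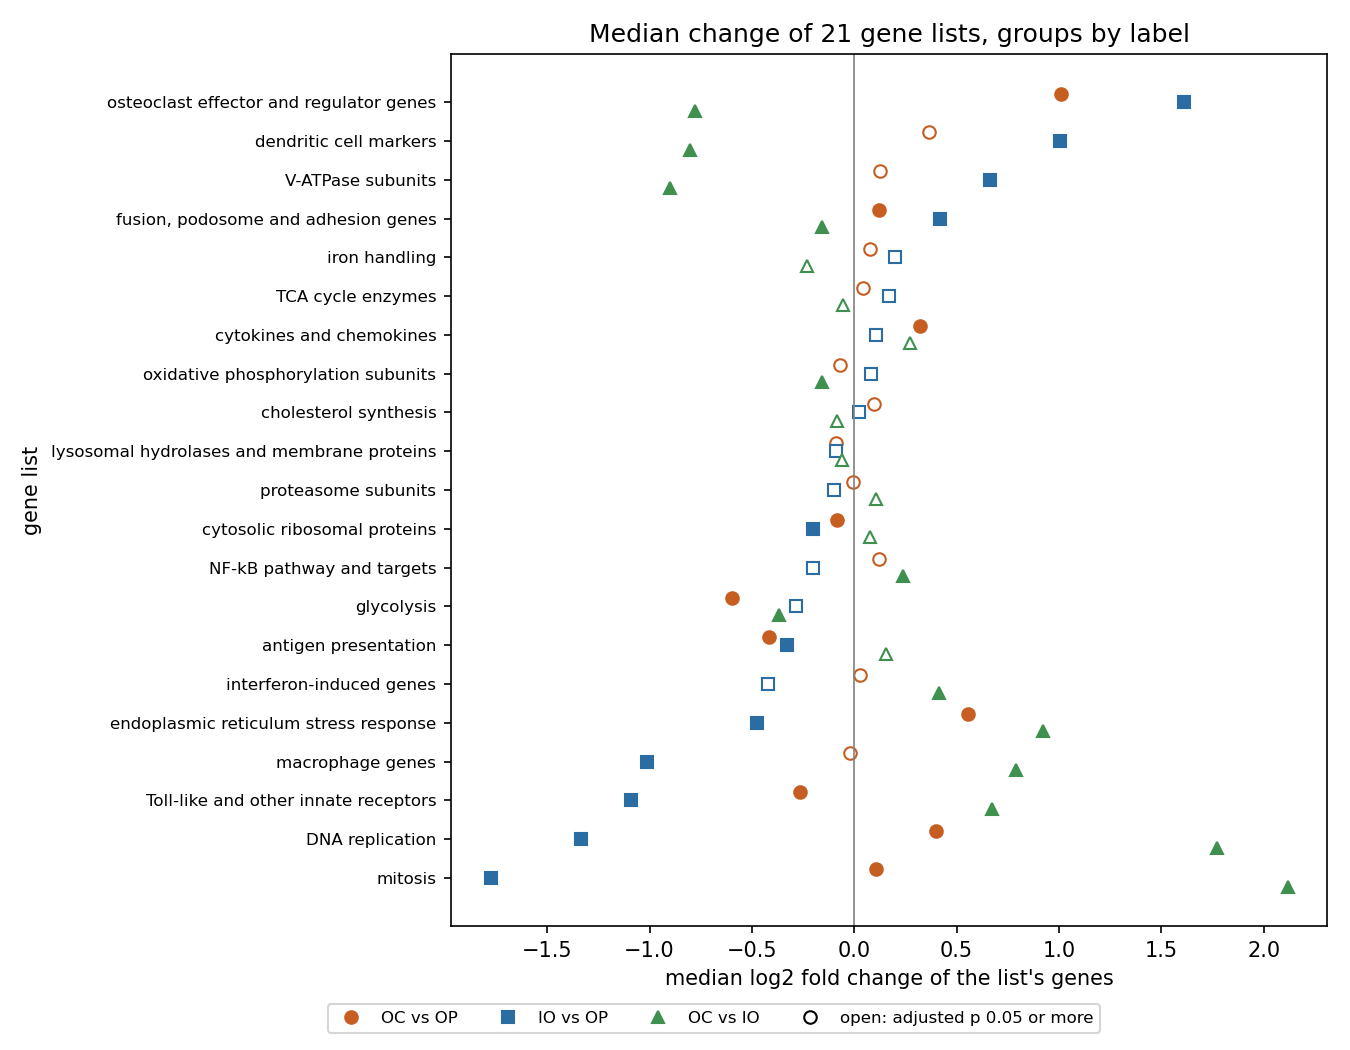
Median log2 fold change (horizontal axis) of the measured genes of 21 lists (vertical axis) for OC vs OP (circles), IO vs OP (squares) and OC vs IO (triangles), with filled symbols where camera gave an adjusted p under 0.05 at its preset correlation. The mitosis list has medians of 0.11, -1.78 and 2.12, and the osteoclast list 1.01, 1.61 and -0.78 (0.83 and 1.42 against OP with genes not above background at their bound).

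Lists that passed in none of the 3 comparisons were lysosomal hydrolases and membrane proteins, tricarboxylic acid (TCA) cycle enzymes, cholesterol synthesis, proteasome subunits and iron handling. Lysosomal genes rose in 2 and fell in 7 of 37 cases in OC vs OP, rose in 9 and fell in 10 in IO vs OP, and were higher in 8 and lower in 13 in OC vs IO, with the same numbers adjusted over the list alone. The lowest camera adjusted p over the 3 comparisons was 0.223 for the lysosomal list, 0.332 for 18 TCA cycle genes, 0.471 for 16 cholesterol synthesis genes, 0.524 for 28 proteasome genes and 0.403 for 17 iron handling genes. The medians of these lists lay between -0.23 and 0.20 on the log2 scale.

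The comparisons with OP share the OP arrays. Of 1254 genes called in both, 1047 moved the same way (535 higher, 512 lower) and 207 opposite ways, against 236.9 higher and 223.2 lower for independent lists, a number that ignores the shared arrays. The correlation of log2 fold changes across genes was 0.468. In 100 simulated draws of unchanged groups sharing their OP arrays it was 0.499 on average. The sharing alone fixes that simulated value whatever the size of the noise, so the correlation cannot test a shared response. The covariance, which keeps the size of the changes, was 0.135 against a simulated 0.0104, above what the shared arrays alone gave. The 3 OP arrays are too few to give each comparison its own.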

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

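No test in this part was chosen only after the result was seen. The 3 arrays below, all on BeadChip 2, have conflicting labels and stand outside every comparison, and all 3 carried osteoclast genes above the OP level when the 12 arrays were normalized together. The mean log2 intensity of 31 osteoclast genes lay 1.679 above the OP mean on the array titled osteo 4, 0.875 above it on the array titled trap 4 and 1.612 above it on the array titled osteo 5. The 3 OP arrays lay between 7.752 and 7.828, the 3 IO arrays between 9.420 and 9.431 and the 3 OC arrays between 8.732 and 8.769.

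For each array it was tested whether the cell subtype in its labels could be right. The array titled osteo 4 has the subtype OP but a RANKL label, and its mean was 1.648 above the highest OP array, against an SD of 0.039 among OP arrays. Over 4417 genes that differed between OC and IO, a position of 0 is the IO mean and 1 the OC mean. The array titled trap 4, of subtype IO, lay at 0.983, and the array titled osteo 5, of subtype OC, at -0.129, while IO arrays lay between -0.050 and 0.074 and OC arrays between 0.985 and 1.017. These values argue against the cell subtype label of each array, although the cell subtypes, unlike the titles, match the number of replicates the series describes. OP arrays lay at 0.970 to 0.996 on this scale, so the position alone does not tell OC from OP, but the osteoclast genes of the array titled trap 4 lay above the OP arrays. A wrong subtype entry stays open as the explanation, and so does an exchange of RNA or arrays, which was not tested. No biological explanation was tested.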

How the results depend on the processing

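The use of BeadChip 1 alone was chosen after seeing the data. Apart from grouping by cell subtype, values of single genes kept their direction and side of the threshold 5565 times, lost a call 273 times, gained a call 5 times and reversed 1 time, and those of lists, an estimated correlation included, kept both 1170 times, lost a call 61 times and gained a call 3 times. Values without a call in either setting changed direction 1 time for genes and 8 times for lists. Grouping the 12 arrays by cell subtype gave 15, 0 and 0 genes for OC vs OP, IO vs OP and OC vs IO (limma; 1017, 1129 and 189 at an unadjusted p under 0.05), 9, 0 and 0 at least 2-fold, and 3 across the groups. Under it the log2 fold changes in IO vs OP of Dhcr7 (-0.013), Mmp14 (0.015) and Psmd2 (0.072) reversed, and the camera direction of the endoplasmic reticulum stress list in IO vs OP turned, with a median of -0.067 and an adjusted p of 0.946. That grouping mixes arrays whose labels conflict. Grouping by title kept 1520 of 1802, 4383 of 4579 and 4255 of 4417 calls in the same direction. Requiring detection on all 9 arrays reversed Itgb1 in OC vs IO (-0.228). That setting leaves the normalized values of a probe unchanged, so another probe stood for the gene. Testing all probes gave 7585 (IO vs OP), 7255 (OC vs IO) and 8930 (3 groups), and 292, 1993 and 1638 at least 2-fold, because it counts probes. In the order OC vs OP, IO vs OP, OC vs IO, counts at least 2-fold were 58, 483 and 379 without background correction, 98, 764 and 623 with an offset of 50, and 66, 533 and 409 with the authors' values; an uncorrected background or a larger offset shrinks folds by construction, and signal over background limits the size of folds of dim genes. Median scaling gave 1033 (OC vs OP) and 2851 (OC vs IO), and the cause was not tested. BeadChip 1 alone, with fewer arrays, gave 1053 in OC vs OP. Of the genes called on it, 97%, 97.2% and 98.2% had the same direction on BeadChip 2. An estimated correlation left 1, 1 and 0 lists (camera; in OC vs IO 10 had an unadjusted p under 0.05).

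Leaving out an array gave 974 to 2174 genes in OC vs OP, 3876 to 4552 in IO vs OP, 3634 to 4412 in OC vs IO and 4569 to 5416 across the groups. The lowest OC vs OP numbers were 974 without OC replicate 1 and 999 without OP replicate 1. The replicate block gave 2005, 4793, 4596 and 5573 genes and 10, 11 and 13 lists. Same-numbered arrays share a number and a BeadChip: 5 of 9 pairs of same-numbered arrays had deviations correlated above 0.1 (from -0.030 to 0.334), and 7 of 9 arrays correlated best with an array of their own number.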

Other observations

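The tests of enrichment, of the order of the IO and OC arrays (apart from the camera test of the osteoclast list) and of the low-oxygen genes were chosen only after the result was seen. Genes called higher on the arrays labelled OC than on both other groups numbered 345 of 8967. They held 18 of 36 DNA replication genes (odds ratio 26.3, Fisher's exact test over 42 combinations, adjusted p = 2.03e-15) and 16 of 27 endoplasmic reticulum stress genes (odds ratio 38, adjusted p = 2.03e-15), as well as 5 of 20 cytokines and chemokines (odds ratio 8.43, adjusted p = 0.00551) and 5 of 31 osteoclast genes (odds ratio 4.86, adjusted p = 0.0285). They also held 5 of 27 mitosis genes (odds ratio 5.75, adjusted p = 0.0197), and the other lists did not pass. Of the 345 genes, 142 were also called lower on the IO than on the OP arrays, and these held 16 DNA replication (odds ratio 55.7, adjusted p = 1.55e-18), 12 endoplasmic reticulum stress (odds ratio 54, adjusted p = 2.32e-14), 5 mitosis (odds ratio 14.6, adjusted p = 0.000475) and 3 of 23 NF-kB genes (odds ratio 9.49, adjusted p = 0.0285). Osteoclast genes (1 of 31, adjusted p = 0.939) and cytokines and chemokines (1 of 20, adjusted p = 0.766) did not pass there, nor did the remaining lists. These counts rest on the same calls as the lists above, so the p-values add no further support. With 18 of 36 DNA replication genes called higher in OC vs OP and 36 in OC vs IO, 18 in both was fixed. Fisher's exact test also treats genes as independent, and genes are not independent replicates. The estimated correlation of the DNA replication list was 0.217. A further 303 genes were below both other groups, while the arrays labelled IO were above both others for 1688 genes and below both for 1593.

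Against the order of the names, 19 of 31 osteoclast genes were lower on the arrays labelled OC than on those labelled IO, while 5 were higher and 7 did not pass (camera adjusted p = 0.000159, and adjusted p = 0.060 with an estimated correlation). The values argue against normalization or background correction. Over 6 processing settings the osteoclast list stayed lower in OC, with the median nearest to 0 at -0.44. Settings that change only the probe filter are among these and do not bear on this explanation. On the OC arrays, a mix of untreated OP-like and IO-like cells would put every gene at a common fraction between OP and IO. This holds only if intensity is proportional to RNA amount, which was not tested and which the SE does not cover. Under that assumption 18 of 23 osteoclast genes spoke against a mix, lying more than 2 SE from the median fraction of 0.264. From the weighted mean of 0.171, 16 did so. Such a mix would also not place 18 of 36 DNA replication genes above both groups. A mix that holds precursors already changed by RANKL was not tested and stays open. Exchanged names and cells named intermediate that truly hold more osteoclast transcripts both stay open. They cannot be told apart, because only the names separate them. Either may give the median of -0.771 in OC minus IO of 17 V-ATPase genes outside the osteoclast list. Either may also give the mitosis median of 2.117. The source name also calls the OC arrays TRAP+, where TRAP is tartrate-resistant acid phosphatase, the product of Acp5. The Acp5 mean log2 was 7.15 on OC, 7.78 on IO and 5.43 on OP arrays. Acp5 lay above OP in both groups, so that label does not decide between the explanations.

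Genes known to respond to low oxygen stood among the largest falls in OC vs OP. A list of further such genes was written after those falls were seen but before the values of its other members were, Hk2 was removed from it before any test because the glycolysis list holds it, and Adm was removed after a first test because it was itself among the 10 largest falls (before adjustment, camera had given 1.22e-07 with Adm in OC vs OP and 0.00273 in IO vs OP). Of the 21 remaining genes 12 fell and 2 rose in OC vs OP (median log2 -0.51, camera of limma, adjusted p = 4.62e-06 over 3 contrasts, 1.54e-06 before adjustment and 0.0131 before adjustment with an estimated correlation). In IO vs OP 11 fell and 4 rose (median -0.53, adjusted p = 0.0115, 0.00767 before adjustment), and the estimated correlation gave 0.102 before adjustment. In OC vs IO the shift did not pass (adjusted p = 0.813). A candidate explanation is a weaker low-oxygen response in the RANKL-treated cultures than in the OP cultures. Oxygen, cell density and medium were not measured here, so what lies behind it was not tested.

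Other splits of the 6 arrays into 3 and 3 gave at most 0 genes (limma; at an unadjusted p under 0.05 at most 519, 378 and 556) in each pairwise comparison, against 1802 (OC vs OP), 4579 (IO vs OP) and 4417 (OC vs IO), with 1 of 10 splits, the real one, as large. So few splits cannot give a share under 0.05. For the 3 groups together, 1 of 100 splits gave as many genes as the real 5379, and the highest other gave 2969. At a share of 0.05 this excludes, for that count, a chance assignment of these arrays to groups. The splits moved arrays freely across BeadChips. They cannot exclude chance differences between cultures, since the arrays of a group may not come from separate cultures.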
